A study of Mus musculus with 2 samples.

How the data were processed

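The libraries were made from retina of mouse embryos at embryonic day 14.5 in the laboratory of John Stamatoyannopoulos for ENCODE, per the labels, which give 2 biological replicates of pooled male and female tissue under the same donor label and separate biosample labels. Per the labels, both libraries were sequenced on more than one Illumina instrument model, and replicate 1 on a model that replicate 2 was not. Instrument and replicate therefore cannot be separated. The assay was DNase-seq on genomic DNA. The labels point to a protocol for nuclei and DNase treatment outside the series, which was not used here.

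The deposited files are peak lists and hotspot lists, 1 of each per library, on mm10 per the labels and the file lists that go with them. Peaks and hotspots were called in each library on its own, per the deposited file lists. The aligner, the caller, their versions and their filters are not given in the sources used here. The deposited peak score is a whole number from 1 to 150 for each peak of 150 bp. Its meaning is not stated, it cannot exceed the peak width, and it was used mainly to describe and rank peaks within a library. The closing section also compares it between the libraries at shared peaks, without deciding a cause. There the ranks drawn from it are compared between libraries at genes of chromosome Y. The hotspot lists of the authors give a −log10 false discovery rate for each hotspot, with a lowest deposited value of 1.30 in both libraries and a ceiling of 100 reached by 34.4% and 38.0% of hotspots. The browser score in the same lists repeats that value and was not used. All peaks lay in a hotspot of the same library.

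In 12.1% and 7.80% of peaks the score was written in decimal form, and these peaks had lower median scores (19 and 31) than the rest (32 and 50). They were kept, and the results without them were computed as an alternative added after the data were seen. Exact duplicate lines (34 and 56) were removed. Peaks on scaffolds (203 and 142) and on the mitochondrial genome (29 and 24) were left out of every comparison with genes. No read numbers were in the files, so the depth of each library is unknown and no detection limit was computed.

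The reference was GRCm38, the same assembly as mm10, with GENCODE release M21 annotation. No peak ran past the end of a chromosome. A promoter was the 1000 bp on either side of any annotated TSS, and a peak overlapping it was a promoter peak. Other peaks were exon, intron or intergenic, in that order. Neighbouring genes can share a promoter window, so a peak can count for more than 1 gene. The promoter rank of a gene is the percentile rank of its strongest promoter peak among all peaks of the library. Distal peaks lay more than 1 kb from any TSS and were assigned to the protein-coding gene with the nearest TSS, which need not be the gene they act on.

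The gene lists, the named loci, the motifs, the tests and most alternatives were fixed before the data were examined. The limits for calling a list high or low (97.5th and 2.5th percentiles in both libraries), the motif ratio of 1.5, the removal of duplicates and the counts of lists and motifs past these limits were set afterwards, before the results were seen. There were 24 lists, of which 23 named their genes (494 of 495 entries matched a protein-coding gene) and 1 held chemosensory receptor genes taken by symbol. Some genes belong to several lists, such as Isl1, Onecut1, Otx2 and Fzd5, so the lists are not independent. For each list and library, the number of members with a promoter peak was placed among 10000 random lists matched in 10 bins of promoter CpG observed over expected, measured 500 bp on either side of the 5' end. The median number of distal peaks was placed among 10000 random lists matched in 10 bins of the length of genome nearest to each gene. Genes are not replicates, so the percentiles describe these libraries and carry no p-value. Shares of genes carry exact Clopper-Pearson 95% intervals.

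Peak lists were compared by an overlap of at least 1 bp with bedtools 2.31.1 and with 100 circular shifts on the assembled nuclear chromosomes. Motifs were matched on both strands as consensus sequences in the central 150 bp of each peak and in flanks of the same width centred 1 kb away on either side. With 1 group there was no contrast between conditions. Values are given per library or as mean and SD over the 2 libraries, and no test between the libraries was possible.

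The genes named were taken by a fixed rule. It took all 26 named loci, with the distal peak shared by both libraries whose lower rank was highest. It took up to 3 members of each list with the highest promoter rank in the lower library and up to 3 without a promoter peak in either, in alphabetical order. It also took the 10 genes with the most distal peaks, the 5 strongest distal peaks on autosomes and X, and per library the 5 list members with the strongest promoter peak in that library alone. The text names a selection of the list members taken, and some loci and genes that the rule takes are not reported here. Alternatives were the stronger part of the peaks by score (upper 50 percent of ranks), equal peak numbers, hotspots in place of peaks, other promoter windows and TSS sets, other distances for distal peaks, gene body plus 50 kb in place of nearest TSS, unmatched random lists, other motif windows and backgrounds, autosomes only, and leaving out each replicate.

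The measures were tested on simulated data. For the overlap of replicates, a planted overlap of 60% came out as 60% over 20000 intervals. For promoter peaks of gene lists over 21938 genes, 0.5% of random lists (nominal share 2.5%) and 100% of lists made open were called high. For distal peaks over the same genes, 3% of random lists and 100% of lists with doubled values were called high. The simulated promoter bins had lower open shares than the CpG-rich bins of the data, so the 100% for promoters does not carry over to lists near the ceiling. The fully open progenitor list stood at the 94.5th and 92.8th percentiles and was not called high. The simulated distal counts were Poisson draws without the long tail of the data, where Tenm3 had 214 and 300 distal peaks. The 100% for distal peaks therefore does not carry over either. Muscle genes in replicate 1 had a median of 3, where random lists averaged 1.45, and at the 95.9th percentile were not called high. For motifs in 20000 sequences, a planted share of 30% came out as 29.3%, and as 0.02% after shuffling. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.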

Results

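DNase-seq marks the stretches of chromatin that the enzyme DNase I can cut, which are mostly promoters, enhancers and insulators in use in a tissue. The data hold 1 group, the retina of mouse embryos at embryonic day 14.5, taken as pooled male and female tissue of the strain labelled B6NCrl, with 2 biological replicates. At this age the mouse retina holds dividing progenitors together with newly born ganglion, amacrine, horizontal and cone cells. No other tissue, age or treatment belongs to the series, so gene groups were compared with random gene lists of the same size and the libraries were compared with each other. The files give no read numbers, so the sequencing depth behind each peak list is unknown.

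Replicate 1 had 165269 distinct peaks and replicate 2 had 219308, a mean of 192288 ± 38211 (SD, n = 2). Broader regions of cutting, called hotspots, numbered 145732 in replicate 1 and 183723 in replicate 2 and covered 54.8 Mb and 81.2 Mb, which is 2.01% and 2.98% of the assembled nuclear chromosomes. Each peak was 150 bp wide apart from 1 peak in each library. The deposited peak score had a median of 29 in replicate 1 and 48 in replicate 2, and its 5th percentile was 10 and 23. Chromosome X carried 3837 and 5396 peaks. Chromosome Y carried 127 and 88, and scaffolds 203 and 142, while each autosome had more peaks in replicate 2.

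Promoters were the most over-represented class of sequence among the peaks. Peaks overlapping a 1 kb window on either side of an annotated transcription start site (TSS) made up 25.9% ± 2.44 (SD, n = 2) of the peaks, against 6.24% of 1362749 windows of the same width placed at random. Introns held 36.0% ± 1.52 of the peaks and 37.0% of the random windows, and intergenic sequence held 34.0% ± 1.14 against 53.7%. Exons outside promoter windows held 4.06% ± 0.213 against 3.04%. Promoter peaks had median scores of 47 and 70 in replicates 1 and 2, intron peaks 26 and 44, and intergenic peaks 26 and 43. Counting only the TSSs of protein-coding genes gave a promoter share of 22.1%, and the share moved with the window from 18.9% at 500 bp to 33.3% at 2 kb.

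The peaks of promoters were shared between the replicates more often than those of introns and intergenic sequence. In replicate 1, 78.3% of promoter peaks, 71.6% of intron peaks and 70.8% of intergenic peaks were overlapped by a peak of replicate 2, and in replicate 2 the shares were 66.4%, 49.7% and 49.6%. Over all classes, 73.1% of the peaks of replicate 1 and 53.9% of those of replicate 2 were overlapped by at least 1 bp. Shifting a list around each chromosome 100 times gave means of 2.48% and 1.82%, with highest values of 2.60% and 1.96%. In the top score decile 98.4% and 97.2% of peaks were overlapped, and in the bottom decile 12.6% and 8.63%. Promoter peaks also had the higher median scores given above. The classes were not compared at equal score, so position and score cannot be told apart here. Across the 120845 overlapped peaks of replicate 1, the score ranks in both libraries had a Spearman correlation of 0.929. Peaks are not independent replicates, so no p-value belongs to this correlation.

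**Figure D1:**
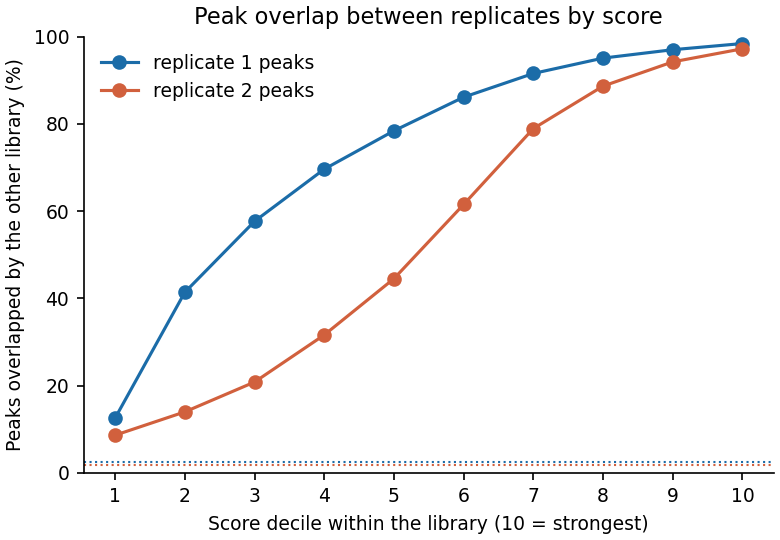
Share of peaks overlapped by a peak of the other library (percent) in each score decile of replicate 1 and of replicate 2, with dotted lines at the mean of 100 circular shifts. The share rises from 12.6% to 98.4% in replicate 1 and from 8.63% to 97.2% in replicate 2.

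Of 21938 protein-coding genes, 15086 (68.8%, exact 95% interval 68.1 to 69.4) had a promoter peak in both libraries. Replicate 1 had one at 15295 genes (69.7%, 69.1 to 70.3) and replicate 2 at 15652 (71.3%, 70.7 to 71.9). These intervals cover counting error only. The share followed the CpG content of the promoter, from 8.84% of genes in the lowest of 10 bins to 99.2% in the highest. For this reason each gene list was set beside 10000 random lists drawn from the same CpG bins.

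Genes of retinal progenitors and of the neurons born at this age had promoter peaks almost without exception. All 20 progenitor genes, all 20 neurogenic genes and all 22 amacrine and horizontal cell genes had one in both libraries, as did 24 of 25 ganglion cell genes and 14 of 15 genes of photoreceptor precursors. The strongest promoter peaks among progenitor genes were those of Lhx2, a LIM homeodomain factor required to form the optic cup, with within-library ranks of 99.8 and 99.9 (100 is the strongest peak), of Hes5, a Notch effector, at 99.9 and 99.7, and of the Wnt receptor gene Fzd5 at 99.7 and 99.3. Neurogenic genes were led by Btg2, an antiproliferative gene of dividing neuron-producing progenitors, at 99.2 and 99.1, and by Sox11 at 99.0 and 99.3. Isl1, a LIM homeodomain gene of ganglion cells, stood at 98.7 and 97.3, and Klf7 at 99.3 in both. Among precursor genes Mef2d (99.3 and 99.9) and Rorb (98.3 and 98.4) ranked high, and Ankrd33 had no promoter peak. Onecut2 (98.9 and 98.0) and Ebf2 (97.1 and 99.1) led the amacrine and horizontal cell genes.

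Random lists matched on CpG came close to these full counts. The progenitor list stood at the 94.5th and 92.8th percentiles of its random lists in replicates 1 and 2, the neurogenic list at 95.0 and 93.4, and the amacrine and horizontal list at 95.3 and 93.7. With every member open a list can go no higher, and 10.9% and 14.4% of the random lists for the progenitor genes were fully open too. The ganglion cell list stood at 95.6 and 99.2 and the precursor list at 96.3 and 94.9.

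Of the 24 lists, 2 passed the 97.5th percentile in both libraries, with 2 passing in replicate 1 and 8 in replicate 2 taken alone. Genes of the optic stalk and ciliary margin were open in 20 of 20 cases (percentiles 99.1 and 98.6), with Tbx3, a T-box factor of the dorsal eye, at ranks of 98.7 and 99.5 and the Hedgehog co-receptor gene Cdon at 98.9 and 97.8. Genes of periocular mesenchyme and neural crest were open in 20 of 22 cases in each library (99.8 and 99.4), 19 of them in both. Among them the growth factor receptor gene Pdgfra ranked 94.2 and 96.4 and the forkhead gene Foxc1 93.6 and 93.1. The collagen gene Col3a1 had no promoter peak. With a 500 bp window, or with the TSS at the 5' end of each gene alone, 1 list passed in both libraries, and with random lists not matched on CpG 9 did.

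Lists of later or neighbouring cell types differed in their counts, as did the random lists matched to them. Phototransduction genes were open in 19 of 32 cases in replicate 1 and 23 in replicate 2 (percentiles 92.6 and 99.6), with Gnat1, the rod transducin gene, at ranks of 95.0 and 96.6 and no promoter peak at Gngt1, Opn1mw or Pdc. Their open members had median promoter ranks of 49.7 and 51.7, and with only the stronger part of the peaks 9 were open in replicate 1, 12 in replicate 2 and 8 in both. Bipolar cell genes were open in 14 and 15 of 19 cases (89.0 and 95.3) with none at Cabp5, Nyx or Pcp2, and Müller glia genes in 16 and 17 of 18 cases (92.2 and 97.4) with Glul, the glutamine synthetase gene, at 99.6 and 99.3. Pigment epithelium genes were open in 11 and 14 of 18 cases (93.3 and 99.9): the melanosome gene Pmel ranked 96.1 and 98.0 and Mitf 95.9 and 96.6, and the visual cycle gene Rpe65 had no promoter peak. Lens genes were open in 11 and 14 of 21 cases (30.9 and 79.3), with Maf at 94.6 and 97.0 and no promoter peak at the crystallin genes Cryaa, Cryab and Cryba4.

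Lists of blood, vessel and other tissues differed among themselves. Microglia and immune genes had a promoter peak in 3 of 18 cases in each library, 2 of them in both, which lay at the 0.450th and 0.175th percentiles, and the complement genes C1qb and C1qc had none. Endothelial genes were open in 9 of 18 cases in each library (2.82 and 1.55), with Kdr at ranks of 95.9 and 98.0 and none at Cdh5. Erythroid genes were open in 6 and 5 of 17 cases (36.3 and 11.3) with no promoter peak at Gata1 or Alas2, and the transferrin receptor gene Tfrc, used by most dividing cells, ranked 99.5 and 99.7. Hepatocyte genes were open in 5 and 6 of 20 cases (4.82 and 6.35) with none at Alb or Apoa1, and epidermal genes in 7 and 9 of 16 cases (23.0 and 54.9) with none at Flg or Ivl. Muscle genes were open in 15 and 16 of 21 cases (96.0 and 97.6), with Mylpf at 99.5 and 98.0 and none at Myf5. Forebrain (telencephalon) genes were open in 15 and 18 of 18 cases (38.1 and 98.4), with Bcl11b at 91.1 and 96.6.

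Hox genes, which pattern the body axis behind the forebrain, were the named list farthest below its random lists. Of 39 members, 24 had a promoter peak in replicate 1, 21 in replicate 2 and 17 in both, where random lists averaged 35.5 and 35.9, and no random list was as low in either library. Hoxa10 ranked 94.0 and 95.9 and Hoxa7 95.9 and 93.4, while Hoxa3, Hoxa6 and Hoxb7 had no promoter peak. Odorant, taste and vomeronasal receptor genes were also below every random list, with 50 and 74 of 1501 open and 30 in both. All 22 cell cycle genes (73.3 and 71.2) and all 20 housekeeping genes (97.2 and 96.2) had promoter peaks in both libraries, among them E2f1 at ranks of 99.7 and 99.5 and Polr2a at 99.9 in both. Genes of Notch, Wnt, Hedgehog, FGF and BMP signalling were open in 32 and 33 of 33 cases (90.6 and 97.8), with Notch1 at 99.5 and 98.0.

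Several lists had more distal peaks per gene than random lists did. Progenitor genes had a median of 20 distal peaks in replicate 1 and 29.5 in replicate 2, where random lists matched on the length of genome nearest to each gene averaged 5.71 and 8.20. No random list reached either value. Amacrine and horizontal cell genes had medians of 19.5 and 33 (random 8.07 and 11.7) and neurogenic genes 10.5 and 13 (2.71 and 3.52), again above every random list in both libraries. Ganglion cell genes had 20 and 31 (percentiles 99.8 and 99.9), photoreceptor precursor genes 16 and 29 (99.0 and 99.9), optic stalk and ciliary margin genes 21.5 and 24 (100 in both after rounding) and signalling genes 15 and 17 (100 in both after rounding). Sox2, a transcription factor of neural progenitors, had 107 and 111 distal peaks nearest to it, Six3 83 and 108, Sox11 62 and 99, and Isl1 44 and 86.

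In all, 10 of the 24 lists passed the 97.5th percentile in both libraries. The others were mesenchyme and neural crest (medians 12.5 and 18, percentiles 99.1 and 99.4), telencephalon (14.5 and 21.5, 99.8 and 99.9) and microglia and immune genes (3 and 3, 99.7 and 98.4). The immune genes thus had few promoter peaks and more distal peaks than matched lists. Phototransduction genes had medians of 2 and 3 (78.6 and 90.3), bipolar genes 7 and 6 (96.0 and 70.0), Müller glia genes 6 and 7.5 (88.1 and 80.9), pigment epithelium genes 4 and 4 (58.5 and 28.8) and lens genes 2 and 3 (74.5 and 85.7). Endothelial genes had 6 and 10.5 (91.3 and 98.4), erythroid 1 and 1 (71.6 and 59.4), Hox 2 and 1 (100 and 90.4), hepatocyte 1 and 1.5 (34.9 and 40.2), muscle 3 and 4 (95.9 and 97.9) and epidermal genes 2.5 and 3 (84.0 and 80.3). Cell cycle genes had 1 and 1 (47.8 and 29.2), housekeeping genes 2.5 and 1 (99.8 and 52.7), and chemosensory receptor genes 0 and 0, below every random list. When distal meant more than 10 kb from any TSS, 5 lists passed.

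**Figure D2:**
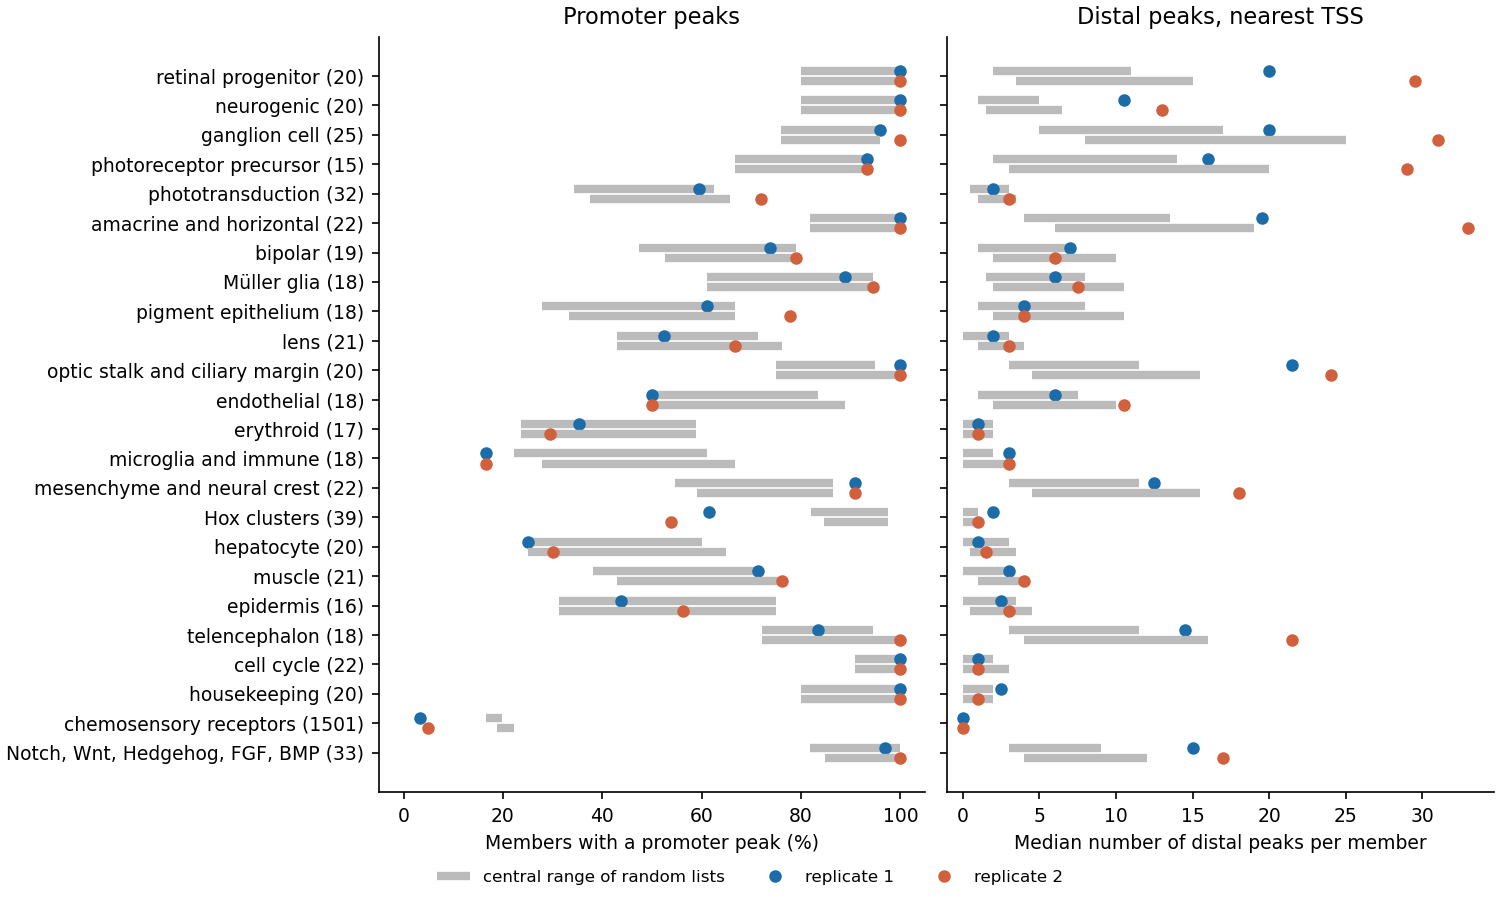
Left, share of each list's members with a promoter peak (percent); right, median number of distal peaks per member, for replicates 1 and 2, with the list size in parentheses and grey bars spanning the middle 95% of 10000 random lists. Progenitor genes lie at 20 and 29.5 distal peaks, and Hox genes lie left of their bars for promoters, with 24 and 21 of 39 members open.

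The number of distal peaks of a gene depends on the length of genome nearest to it, and the genes with the most distal peaks in both libraries mostly had long stretches. Tenm3, a teneurin gene, had 214 in replicate 1 and 300 in replicate 2 within 2.97 Mb, where the genome averages over that length would give 130 and 181. The zinc finger genes Zfp608 (176 and 241 within 1.28 Mb, averages 56.2 and 78.2) and Zfhx3 (161 and 248 within 1.34 Mb, averages 58.7 and 81.7) came next. Adgrl2 had 140 and 209 within 2.33 Mb (102 and 142 by the averages), Basp1 124 and 121 within 1.22 Mb (53.7 and 74.7), and Auts2 115 and 227 within 1.94 Mb (85.0 and 118). Celf4, with 116 and 161 within 2.65 Mb, had as many as the averages give (116 and 162), and Rbfox1, with 108 and 169 within 2.32 Mb, came near them (102 and 141). Robo1 had 107 and 138 within 2.02 Mb (88.5 and 123), and Zmiz1 114 and 110 within 0.700 Mb (30.7 and 42.7).

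At the loci named in advance, peaks were counted over the gene body plus 50 kb on either side and set per 100 kb, where the genome averages were 6.06 in replicate 1 and 8.04 in replicate 2. Sox2 had 57.8 and 58.8 peaks per 100 kb, Pax6 51.4 and 55.3, Six3 50.1 and 59.6, Rax 40.4 and 37.7, Six6 26.7 and 31.4, and Lhx2 27.6 in both. Loci of other classes reached similar values: Otx2 30.1 and 43.1, Olig2 32.0 and 32.9, Isl1 20.6 and 43.1, Neurog2 17.6 and 33.2, Onecut1 38.5 and 21.6, and Nrl 33.0 and 21.7. A window can hold promoters of neighbouring genes, and no windows of other genes were set beside these values. That of Nrl also holds Carmil3, Cpne6, Pck2 and Dcaf11, among others, and only 3 distal peaks in each library were nearest to Nrl. Atoh7, the bHLH gene needed for ganglion cell birth, had 18.7 and 20.7, Neurod1 19.2 and 17.3, Pou4f2 20.3 and 25.1, Ptf1a 23.6 and 22.6, Prdm1 14.6 and 15.7, Vsx1 12.88 and 11.04, Mitf 9.23 and 12.4, Crx 11.4 and 7.89, and Thrb 3.56 and 6.91. Without a promoter peak, Cryaa had 17.3 and 22.1 and Alb 3.46 and 7.78. In numbers of peaks, Onecut1 (50 and 28) and Nrl (35 and 23) had more in replicate 1. Within the stronger part of the peaks Onecut1 had 22 and 21 and Nrl 18 and 19. Genome-wide that part held 82634 and 109654 peaks, a ratio of replicate 2 over replicate 1 of 1.33. Both loci thus stayed below that ratio, on small counts and without a test. Isl1, with 23 and 48 peaks, had 14 and 25 in the stronger part.

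At each named locus the distal peak with the highest rank in both libraries was located. At Prdm1, a gene of photoreceptor precursors, the peak lay in an intron of the gene at chromosome 10, 44493256 to 44493405 (mm10), with scores of 79 and 112. Its sequence, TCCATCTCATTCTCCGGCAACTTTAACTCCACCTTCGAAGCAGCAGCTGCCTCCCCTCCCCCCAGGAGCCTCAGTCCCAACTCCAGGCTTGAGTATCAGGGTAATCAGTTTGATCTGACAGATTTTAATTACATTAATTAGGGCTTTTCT, holds TTAATTAG at 44493389, the paired-class match TAATTACATTA at 44493381 and the E-box GCAGCTGC at 44493298. At Atoh7 the peak lay in an intron of Pbld1 at chromosome 10, 63066096 to 63066245, 33.5 kb upstream of Atoh7 and 1295 bp from a TSS of Pbld1 (scores 96 and 125). At Thrb it lay within an intron of the gene at chromosome 14, 17733856 to 17734005 (97 and 129). At Pax6 it lay 8669 bp upstream of the gene in an exon of a noncoding transcript at chromosome 2, 105660156 to 105660305 (108 and 133). The distal peaks chosen in the same way at Sox2, Crx, Onecut1, Nrl and Cryaa each held a match to the core of the CTCF motif, such as CCACTAGATGGC at chromosome 9, 74905041 for Onecut1.

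**Figure D3:**
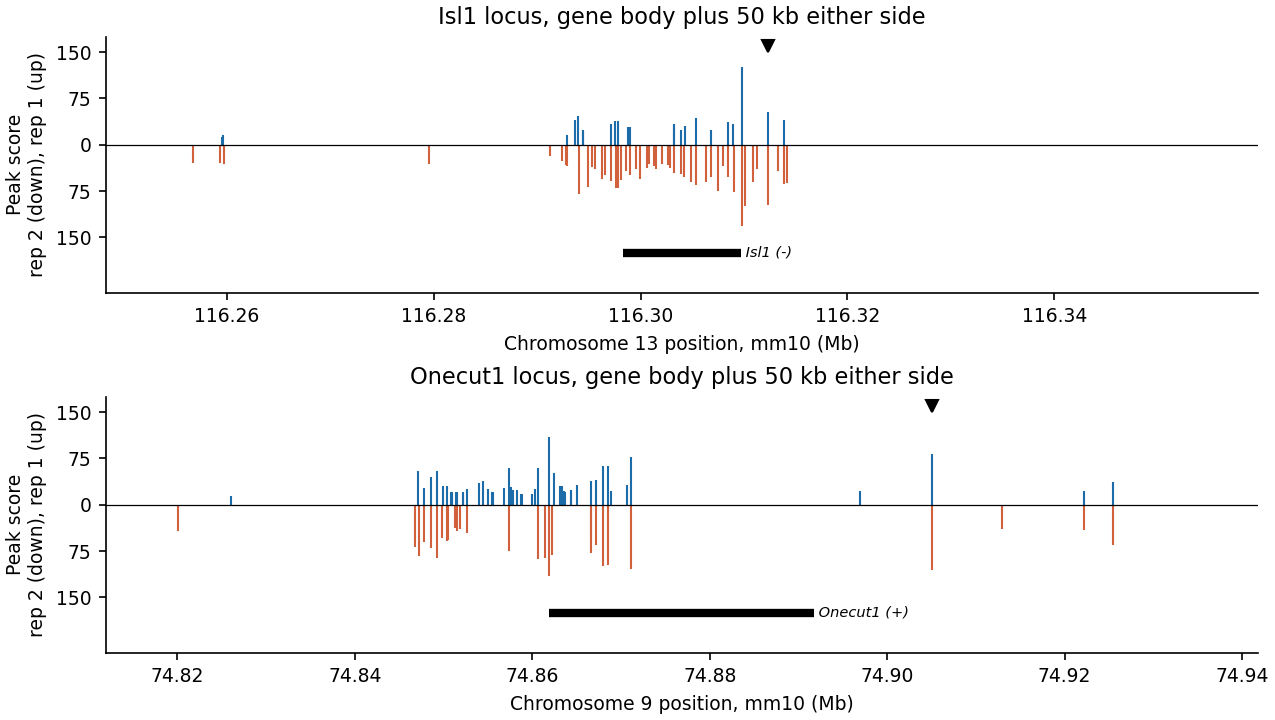
Peak scores of replicate 1 (upward) and replicate 2 (downward) across the Isl1 and Onecut1 loci in mm10 coordinates (Mb), with protein-coding genes as black bars and a triangle over the highest-ranked distal peak shared by both libraries. The Isl1 locus has 23 and 48 peaks (14 and 25 in the stronger part of the peaks) and the Onecut1 locus 50 and 28 (22 and 21).

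The 5 strongest distal peaks shared by both libraries lay on chromosomes X, 15, 1, 6 and 11. The top peak lay in an intron of Gm21887 on chromosome X, 170017476 to 170017625, with scores of 141 and 145. The next lay 52178 bp from the nearest coding TSS, that of Wnt7b, at chromosome 15, 85634576 to 85634725 (136 and 145). Others were nearest to Ptma (chromosome 1, 86487496 to 86487645, 140 and 143) and Ezh2, a Polycomb histone methyltransferase gene (chromosome 6, 47651196 to 47651345, 137 and 143), and in an intron of Mnt (chromosome 11, 74832196 to 74832345, 135 and 143). The Mnt peak lay only 1351 bp from a TSS of that gene.

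Among 24 consensus motifs, 8 were enriched at least 1.5 times in the centres of distal peaks over flanks 1 kb away in both libraries. CTCF, the insulator protein, led with a ratio of 36.7 ± 3.83 (SD, n = 2), and its core motif occurred in 5.06% and 3.94% of distal peaks. Motifs of the RFX family (12.9 ± 2.05) and the NFI family (9.50 ± 2.01) followed, the NFI value resting on a match in 0.0594% and 0.0632% of peaks. The nuclear receptor motif of ROR factors had a ratio of 3.67 ± 0.584, NRF1 3.51 ± 0.169, the CAGCTG E-box bound by Ptf1a 2.72 ± 0.0816, the palindromic MEIS motif 2.43 ± 0.298 and the SOX motif 2.38 ± 0.0560. Matches of NRF1 (0.0510% and 0.0469% of peaks) and of the palindromic MEIS motif (0.0653% and 0.0662%) were about as rare as those of NFI. The TAATTA homeodomain motif of Lhx2 and Rax had ratios of 1.43 and 1.75, the ONECUT motif 1.15 and 1.56, the ETS motif (matched in 0.0535% and 0.0607% of peaks) 1.42 and 1.73, the SP and KLF motif 1.45 and 1.69, and the short MEIS core 1.49 and 1.61. The TEAD motif had ratios of 1.32 and 1.35, AP-1 1.27 and 1.32, NF-Y 1.25 and 1.27, MEF2 1.12 and 1.28, and the paired-class dimer 0.979 and 1.23. Below 1 were the GATA motif (0.675 and 0.687), the liver and gut motif of HNF4 (0.996 and 0.937), the OTX and CRX motif (0.868 and 0.972), the POU4F motif (0.490 and 0.669) and the CATATG E-box of Atoh7 and Neurog2 (0.553 and 0.556). With shuffled sequence of the same dinucleotide content in place of flanks, the OTX and CRX, POU4F and CATATG values turned above 1 and the NF-Y value below 1, and 16 motifs passed in both libraries.

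Promoter peaks had 8 motifs past the same ratio in both libraries, and they were partly different ones. NRF1 (7.64 ± 1.47, SD, n = 2), ETS (6.47 ± 0.718), SP and KLF (3.50 ± 0.0230) and NF-Y (2.85 ± 0.163) reached higher ratios than in distal peaks, and CTCF (10.8 ± 0.548), RFX (6.31 ± 0.841), NFI (6.32 ± 0.763) and the CAGCTG E-box (1.68 ± 0.0490) lower ones. The TAATTA motif stood at 0.648 and 0.875 and the ONECUT motif at 0.481 and 0.678. Both turned above 1 with shuffled sequence, at 2.22 and 1.61, and 15 motifs then passed.

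**Figure D4:**
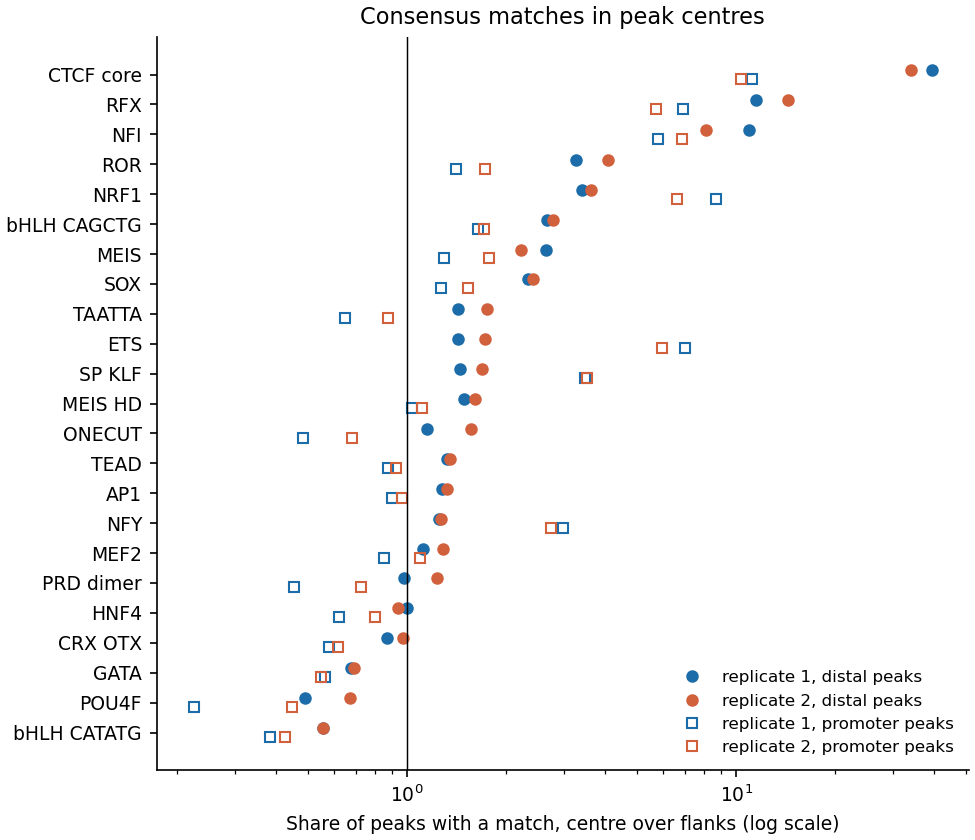
Ratio of the share of peaks with a motif match in the central 150 bp to the share in flanks 1 kb away (log axis) for distal peaks (filled circles) and promoter peaks (open squares) of replicates 1 and 2, without the p53 motif, which had almost no matches. CTCF reaches 39.4 and 33.9 in distal peaks, and NRF1 8.68 and 6.60 in promoter peaks.

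Members of the 23 lists of named genes that had a promoter peak in only 1 library numbered 11 for replicate 1 and 27 for replicate 2. The strongest seen in replicate 1 alone were the Hox genes Hoxb6 (rank 64.0), Hoxd3 (62.9), Hoxb13 (60.5) and Hoxb8 (59.3), and the bipolar cell gene Bhlhe23 (57.9). In replicate 2 alone they were Hoxa9 (75.4), Hoxb9 (72.9), Shh, the Hedgehog ligand made by ganglion cells (72.9), Neurod2 (65.5) and Hoxb2 (62.7). Hox genes made up 7 of the 11 and 4 of the 27. With equal numbers of peaks per library the counts were 14 and 21. A single library stands on each side, so no test of this difference was possible.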

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

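The tests of all 3 patterns weighed here were chosen after the values they explain had been seen. The design names no biological difference between the libraries, so no biological explanation other than cell content was tested. Instrument models differed between the libraries per the labels, cannot be separated from replicate and were not weighed. Differences in cell content were weighed as possible mixtures only (6.36, 2.76 and 28.6% below). Peaks outside the nuclear chromosomes were used in no comparison with genes. The mitochondrial genome carried 29 peaks in replicate 1 and 24 in replicate 2, of which 15 and 14 had the highest possible score of 150. Unplaced and unlocalised scaffolds carried 203 and 142 peaks.

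Replicate 2 had 219308 peaks against 165269. A looser hotspot threshold in replicate 2 is argued against, since the lowest deposited −log10 false discovery rate was 1.302 in both libraries and all peaks lay in hotspots, but a threshold for peaks within hotspots stays open. Cell types missing from replicate 1 stay open too: 2.76% of the top score decile of replicate 2 had no peak in replicate 1, against 1.56% the other way round, but cell types that make up little of the tissue would give weak peaks. More sequenced or more cut DNA could not be decided either, since the peaks seen in 1 library alone lay mostly in the lower 50 percent of its ranks in both (88.6% in replicate 1 and 82.3% in replicate 2). The deposited score was higher in replicate 2 at 99.5% of the 120845 shared peaks, which a rise in depth or cutting over the whole genome would give and missing cell types alone would not, but the score's meaning and scale are not stated, so read numbers would be needed to decide.

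On chromosome Y the order was reversed, with 127 peaks in replicate 1 and 88 in replicate 2, where the autosomes had ratios of replicate 2 over replicate 1 from 1.24 to 1.42. The loss lay beyond the last single-copy gene at 2.66 Mb (108 and 66), while the part before it had 19 and 22. Repeats wherever they lie and the decimal-form peaks are argued against, because autosomal peaks lying mostly in repeats had a ratio of 1.37 and the Y ratio without decimal-form peaks was still 0.731. A smaller share of male cells in replicate 2 could not be decided: the promoter ranks of the 4 Y genes with a peak (Ddx3y, Eif2s3y, Kdm5d and Uty, chosen after the values were seen) moved by a median of 6.36, the 87.1th percentile of matched autosomal sets, which goes against a loss but rests on 4 genes. Repeated sequence on chromosome Y itself stays open and was not tested: 72 and 37 of the Y peaks lay mostly in repeats, and scaffolds also had fewer peaks in replicate 2 (203 and 142).

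The Hox clusters were singled out from all lists after their values were seen, because 7 Hox promoters were open in replicate 1 alone and 4 in replicate 2 alone, the reverse of the sum over the other lists. Over the clusters replicate 1 had 183 peaks and replicate 2 had 118, and the direction was not uniform: Hoxd had 82 and 18 and Hoxb 50 and 28, while Hoxa had 41 and 54 and Hoxc 10 and 18. A lean of replicate 1 towards CpG-rich promoters was read from 492 genes outside the Hox list, open in 1 library and in the same CpG bins. Of these, 23.0% (exact counting interval 19.3 to 26.9) were open in replicate 1, but most lay in bins 3 and 4 of 10. The Hox genes open in replicate 1 alone lay in bins 4, 5, 7 and 8. Other genes there numbered 38 and 131, 14 and 55, 2 and 7, and 0 and 5 in replicates 1 and 2 alone, which argues against a lean in these bins. The CpG-richest bins, 9 and 10, had 2 and 2 and 3 and 3 genes, too few to decide. Weak peaks alone stay open: the ratio of replicate 2 over replicate 1 went from 0.645 to 0.892 in the stronger part of the peaks, where Hoxa (28 and 38) and Hoxc (10 and 14) followed the genome-wide 1.33, Hoxb (33 and 21) and Hoxd (31 and 18) did not, and the counting interval lay below it over all clusters (0.665 to 1.20), without Hoxc (0.610 to 1.15) and without Hoxa (0.494 to 1.03) but included it without Hoxd (0.731 to 1.45) and without Hoxb (0.717 to 1.44). Cells of another body region in replicate 1 could be a source, but only 28.6% of the discordant members of 6 lists of other tissues (2 against 5) were open in replicate 1 alone, too few to decide.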

How the results depend on the processing

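The alternative without decimal-form peaks was chosen after the data were seen, and it moved no count of lists, genes or motifs by over 1.5 times. The stronger part of the peaks gave a mean of 96144 peaks, an overlap of 80.0% (63.5% with all peaks), a promoter share of 35.8% and 0 lists low in distal peaks. The first follows from its construction. So does the direction of the promoter share below for other windows and for coding TSSs, since a narrower window or fewer TSSs can only lower it. For the others, as for all other values below, the cause was not tested. The promoter share was 22.2% for hotspots, 18.9% and 33.3% for windows of 500 bp and 2 kb, and 22.1% for coding TSSs. Lists high in promoter peaks numbered 1 with a 500 bp window, 1 with the 5' end alone and 9 with unmatched random lists, and 2 to 8 when a replicate was left out. Lists high in distal peaks numbered 5 beyond 10 kb, and lists low in them 0 beyond 2 kb and 0 beyond 10 kb. With shuffled sequence, 16 distal and 15 promoter motifs passed, and leaving out a replicate gave 9 to 13 distal motifs. The 9, those of replicate 1, include the p53 motif, matched in only 0.00167% of its distal peaks.

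In the stronger part of the peaks, members open in both libraries fell from 19 to 8 for the phototransduction list, from 5 to 3 for the hepatocyte list and from 30 to 8 for the chemosensory receptor list. Motif ratios that crossed 1 did so mostly with shuffled sequence. In distal peaks these were NF-Y (0.779), OTX and CRX (1.74), POU4F (2.92) and CATATG (1.40). In promoter peaks they were OTX and CRX (1.53), TAATTA (2.22), the paired-class dimer (2.63), POU4F (3.58), CATATG (1.28), ONECUT (1.61), TEAD (1.37), AP-1 (1.07), MEF2 (3.5) and HNF4 (1.16). The short MEIS core in promoters fell to 0.958 in the stronger part of the peaks, and the distal OTX and CRX ratio was 1.03 in the central 50 bp. Of the other values of single lists, motifs and peak classes, 641 stayed within 1 SD over the libraries or, for counts, within 1.5 times the main value, and 258 moved further without crossing. With 2 libraries, leaving out a replicate cannot move a mean by 1 SD. The values other than counts under that alternative are thus among the 641 by construction and show no stability. All peaks lay in a hotspot, so requiring this changed nothing, and leaving out a replicate leaves no pair for the overlap. No paired analysis was possible because there is 1 group. Unknown depth limits how far absent peaks can be read.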

Other observations

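The lists in this part were chosen after the data had been examined, and they describe the libraries without a test. Mouse counterparts of 30 genes whose mutation causes small, absent or malformed eyes in people had promoter peaks in 28 cases in replicate 1 and in 30 in replicate 2, at the 89.0th and 99.8th percentiles of random lists matched on CpG. They had medians of 18.5 and 23.5 distal peaks, at the 100th percentile of matched random lists in both libraries. The list overlaps the retinal lists (Sox2, Otx2, Rax, Pax6 and others), so it is not independent of them. Among genes outside those lists, the chromatin remodeller gene Chd7 had 50 and 84 distal peaks with promoter ranks of 97.7 and 96.4, Mab21l2 had 15 and 29 with ranks of 94.0 and 96.6, and the retinoic acid receptor gene Rarb had 24 and 41 with ranks of 95.2 and 94.5. The coactivator gene Yap1 had a strong promoter peak (97.5 and 96.6) and 1 and 3 distal peaks.

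A chosen list of long noncoding RNA genes, some of eye and brain and others of wide or imprinted use (Snhg11 among them is annotated as protein-coding), had promoter peaks in 18 of 19 cases in both libraries. Of all 5854 annotated lincRNA genes 26.1% had one in both, but the list was picked by hand from well-studied genes and was not matched on CpG content, so the shares are not comparable. Tug1, needed for photoreceptor development, ranked 97.5 and 99.9, Malat1 97.3 and 98.9, Six3os1 92.1 and 95.9, Vax2os 95.2 and 96.1, and Sox2ot 90.8 and 93.4. Xist, the transcript that silences an X chromosome in female cells, ranked 80.7 and 86.9 in these pools of both sexes. The imprinted gene H19 had a promoter peak in replicate 2 alone (72.9).

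The CTCF motif was concentrated in the strongest distal peaks. It occurred in 0.226% of the lowest score decile of distal peaks and 21.2% of the highest in replicate 1, and in 0.535% and 16.7% in replicate 2.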
